A study of Rattus norvegicus with 8 samples.

How the data were processed

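RNA-seq was analysed from 8 libraries of rat (Rattus norvegicus) nucleus pulposus cells, the cells of the gel-like core of the intervertebral disc. Per the labels, total RNA was isolated with TRIzol, cDNA was made with SuperScript II reverse transcriptase, and paired-end reads were obtained on an Illumina NovaSeq. Whether RNA was selected by poly(A) tail or depleted of ribosomal RNA is not given in the sources used here. Samples were placed in groups by their titles and genotype labels: 4 libraries titled as controls with genotype WT (SOD1-WT) and 4 titled and labelled as SOD1 with the K123R substitution (SOD1-K123R). Both groups carry the same treatment label, lactate, at 10 mM for 7 days per the series design text. The columns of SOD1-WT samples are headed Ctrl and those of SOD1-K123R samples L, a letter that the labels do not expand. If L stood for lactate and Ctrl for cells without it, the differences would reflect lactate as well as or instead of the substitution, and nothing analysed here tests this. The labels do not say whether the replicates of a group were separate cultures, so p-values measure only the spread between these samples, which may be technical. Library identifiers in the labels form 1 unbroken run for each group, so any difference in handling between the runs and the group difference cannot be told apart.

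The authors deposited a single gene-level table of TPM, a measure of transcript abundance scaled for transcript length and library size, with Ensembl gene identifiers, symbols, biotypes and GO and KEGG annotation, per the file headers. The table's name gives RSEM as the source of the TPM. DESeq2 is named by the authors, per the labels' processing notes, without a stated role. The aligner, the genome build and the annotation release are not given in the sources used here, so no coordinates are reported. TPM keep no read counts, so the depth of each library is unknown and no counting interval could be set.

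The table analysed here held 4226 genes, of which 3448 were protein-coding, 762 were long noncoding RNAs and 16 were of other kinds; 827 had no symbol. Its TPM columns summed to between 187515 and 243393 and not to the full total that TPM have over all genes of a library, so the rows are part of a larger set of genes. The rule that chose the rows is not given in the sources used here. Among genes tested, 244 of 2890 (8.44%) had an absolute log2 fold change under 0.5, and genes close to a fold of 1 were therefore scarce. Counts of passing genes, the Benjamini-Hochberg adjustment and the background of the gene set tests all refer to these rows and not to the transcriptome. A gene outside the rows was not analysed here, which says nothing of its level. This holds for Sod1, whose level was to be compared between the groups, although TPM cannot show the substitution itself.

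Genes with a mean of at least 1 TPM over the 8 libraries were tested (2890 genes; 1336 lay below). Values were transformed to log2(TPM + 1), and SOD1-K123R minus SOD1-WT was fitted with limma 3.58.1 (lmFit, then eBayes with a mean-variance trend) in R 4.3.3. Tests were two-sided, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(TPM + 1) scale, which understates changes of genes with low TPM. Errors of TPM are standard deviations over the 4 libraries of a group, and errors of log2 fold changes are limma's moderated standard errors (SE). Several named families, among them ribosomal proteins, ferritins, metallothioneins and glutathione transferases, have near-identical copies or pseudogenes, and their TPM are uncertain where reads were split between copies.

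The model, the filter, 34 gene lists, the rule for naming genes and the alternatives were fixed before the data were examined. By that rule the text names the 8 genes with the largest log2 fold change in each direction among passing genes with a symbol that is not a locus name, groups that do not overlap and a mean of at least 5 TPM in the higher group. It then names up to 3 members of each list with the smallest adjusted p, whichever their direction. Members named because they went against the rest of their list, or did not pass, were chosen after their values were seen. Some single-gene results are not reported here, and those genes were also left out of the comparison of libraries within groups. Of 792 different list members, 240 were in the table, 2 of them through an unambiguous synonym in a RefSeq gene table of the GRCr8 assembly, which was used for names alone. A member called measured below was among these rows and tested. Counts of members that rose or fell are therefore conditional on the unknown choice of rows. The rule for synonyms was revised for the identity of the genes, but after results of the lists had been seen; the count with exact symbols is among the alternatives. Symbols carried by more than 1 gene identifier (6 in the table, Fosl1 among them) enter with each identifier. Lists with at least 5 tested members (20 of 34) were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 20 lists, and again with an estimated correlation and with fry. A camera test compares a list with the other genes tested, most of which changed themselves.

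After the table had been seen, GO and KEGG terms of 10 to 300 tested genes were compared between genes that passed as higher and as lower with Fisher's exact test (402 GO terms and 128 KEGG pathways, adjusted within each), and lists of clock genes and of mitochondrial rRNAs were added. Alternatives were pseudocounts of 0.1 and 0.5 TPM, no filter and a filter at 5 TPM, median-of-ratios and quantile scaling, removal of mitochondrially encoded genes, a replicate block, library weights, a robust variance trend and leaving out each library in turn.

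The procedure was tested on simulated data with the means and spread of the 2890 tested genes, 200 of them changed by known folds. It recovered 76.1% of genes changed 1.5-fold, 98.5% of those changed 2-fold and 100% of those changed 4-fold, with 4.19% of its calls false. A simulated 2-fold shift of 1 of 20 lists was recovered by camera, and 0 of the other lists were called. The simulation varied each gene independently and left 2690 genes unchanged, whereas most tested genes changed in the data. It therefore cannot show how camera, or the share of false calls, behaves with correlated genes or with these rows. Figures were drawn with matplotlib 3.10.9.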

Results

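Gene expression was measured by RNA-seq in rat nucleus pulposus cells, the cells of the core of the intervertebral disc. In these cells SOD1, the cytosolic copper-zinc superoxide dismutase, had been knocked down and then supplied again as the wild-type protein (SOD1-WT, 4 libraries) or as the K123R form, in which a lysine is replaced by arginine (SOD1-K123R, 4 libraries). Both groups were kept in 10 mM lactate for 7 days, and the comparison asks how the substitution changes expression in the presence of lactate. The groups follow the labels, but the table heads the SOD1-WT columns Ctrl and the SOD1-K123R columns L, which the labels do not expand. Sod1 was not analysed here, and its TPM could not have shown the substitution. The level of SOD1 in each group is therefore unknown, and a difference in it cannot be told apart from the substitution. No library labelled as without lactate or without re-expression of SOD1 was analysed here. The deposited values were TPM for part of the transcriptome, amounting to 19.3% ± 0.526 of the full TPM total of a library in SOD1-WT and 24.0% ± 0.334 in SOD1-K123R (mean ± SD, n = 4 each). Sequencing depth is not recoverable from TPM.

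The groups differed in 95.7% of the genes tested from the deposited table. In SOD1-K123R cells 27 of 31 measured proliferation genes fell, while 12 of 13 p53 targets, the glucose transporter gene Slc2a1 and the angiogenic factor Vegfa rose. Rem2, a small GTPase that regulates calcium channels, rose from 2.90 ± 0.801 to 173 ± 11.3 TPM, and Nr1d1, a nuclear receptor of the circadian clock, rose from 9.01 ± 0.932 to 195 ± 18.1 TPM (mean ± SD, n = 4 each, as for all TPM that follow). Tlr2, a receptor for bacterial lipoproteins, fell from 178 ± 19.9 to 9.08 ± 1.20 TPM, and Bmp2, a growth factor of bone and cartilage formation, fell from 148 ± 12.2 to 11.8 ± 2.37 TPM.

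Of 2890 genes tested, 2765 (95.7%) passed in limma at a Benjamini-Hochberg adjusted p under 0.05. Of these, 1289 were higher and 1476 lower in SOD1-K123R, and 751 and 1036 of them changed at least 2-fold. The values of the groups did not overlap for 2641 genes (91.4%, where chance gives 2.86%). The first principal component separated the groups and held 92.6% of the variance. Correlations across genes were 0.981 to 0.994 within groups and 0.788 to 0.818 between them. The rows of the table held few genes near a fold of 1, so these shares do not describe the transcriptome. The rows may also have been chosen for a difference between these groups, so the comparison with 2.86% cannot exclude chance. The balance of directions turned with the processing: at a mean TPM of at least 5, 948 genes were higher and 897 lower (576 and 729 at least 2-fold), and after median-of-ratios scaling 1359 were higher and 1363 lower (1122 and 555 at least 2-fold).

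The other genes with the largest increases were Lrrc32 (log2 fold change 4.07, SE 0.10), a surface docking receptor for latent TGF-beta, Gadd45b (3.99, SE 0.11), a stress-induced growth-arrest gene, and Bhlhe41 (3.77, SE 0.16), a repressor in the circadian clock. Rasd2, a Ras-like GTPase, rose from 0.135 ± 0.0723 to 14.3 ± 1.66 TPM. Eeig1, an estrogen-induced regulator of osteoclast formation, rose by a log2 fold change of 3.71 and Pdk4, a kinase that inhibits pyruvate dehydrogenase, by 3.67. Among the largest decreases were Ism1 (log2 fold change -4.06, SE 0.19), a secreted protein, Pclaf (-3.66, SE 0.11), a PCNA-binding protein, and Gsta2 (-3.47, SE 0.24), a glutathione transferase. Chsy3, a chondroitin sulfate synthase, had a log2 fold change of -3.43, Gjb2, which encodes the gap-junction protein connexin 26, of -3.27 and Krtap11-1, a keratin-associated protein, of -3.23. The highest adjusted p among these 16 genes was 4.34e-08 (limma, Benjamini-Hochberg). Rem2 read 156 TPM in SOD1-K123R replicate 2 and 177 to 181 TPM in the rest of its group.

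**Figure D1:**
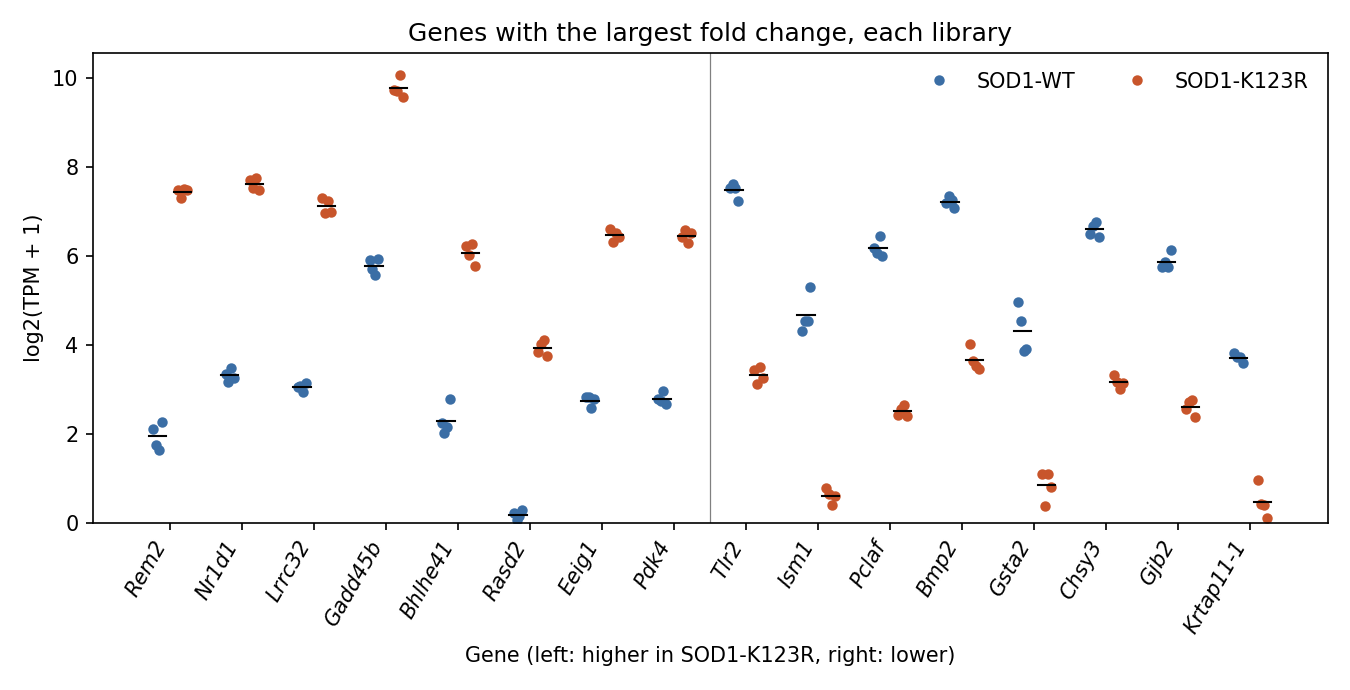
Expression of the 16 genes with the largest fold changes, as log2(TPM + 1) in each library (points) with group means (lines). SOD1-WT libraries are blue and SOD1-K123R libraries orange, and the groups do not overlap for any of the 16 genes.

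Proliferation genes were lower as a group. Of 31 measured members, 27 fell, 0 rose and 4 did not pass (log2 fold changes of -0.33 for Bub1, -0.24 for Hmmr, -0.03 for Kif23 and -0.16 for Prc1). Mcm7, a subunit of the replicative helicase, fell from 49.5 ± 4.05 to 9.94 ± 0.873 TPM. E2f1, a transcription factor of S-phase entry, fell from 24.0 ± 2.59 to 4.04 ± 0.556 TPM, and Tyms, which makes thymidylate for DNA synthesis, fell from 24.3 ± 4.39 to 5.29 ± 0.828 TPM. The list was called by camera (adjusted p = 0.000577), but not with the correlation between its genes estimated from the data (adjusted p = 0.516 with an estimated correlation).

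Targets of the tumour suppressor p53 went the other way. Of 13 measured, 12 rose and 1, Tigar, fell (log2 fold change -1.59). Gdf15, a secreted stress cytokine, had a log2 fold change of 3.32 (SE 0.09), Gadd45a, a growth-arrest gene, of 3.50 (SE 0.14) and Mdm2, the ubiquitin ligase that degrades p53, of 2.08 (SE 0.11). Gadd45a read 425 TPM in SOD1-K123R replicate 4 and 561 to 586 TPM in the rest of its group. The camera adjusted p was 0.000873, against an adjusted p = 0.273 with an estimated correlation. In the list of cell cycle arrest and senescence genes 5 of 9 rose and 4 fell (camera adjusted p = 0.450). Those that rose included Cdkn1a, the p53-induced kinase inhibitor p21 (236 ± 46.2 to 1046 ± 47.8 TPM), Cdkn1b, the kinase inhibitor p27 (25.3 ± 2.26 to 90.6 ± 9.42 TPM), and Bhlhe40 (log2 fold change 3.32). The 4 that fell were H2ax, Rb1, Hmgb2 and Lmnb1. The fall of Lmnb1 (log2 fold change -0.66) was not followed singly under median-of-ratios scaling, which shifted the typical log2 fold change by 0.39. Loss of Hmgb2 and Lmnb1 is itself a known mark of senescence, so members that move together in senescence count in opposite directions here, and neither the count nor the test measures senescence.

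Genes of the unfolded protein and integrated stress responses rose in 10 of 12 cases. Ddit3, the transcription factor CHOP, rose from 35.1 ± 3.74 to 372 ± 7.44 TPM, Hspa5, the main chaperone of the endoplasmic reticulum, from 941 ± 84.2 to 4118 ± 271 TPM, and Atf3, a stress-induced transcription factor, from 4.33 ± 0.832 to 34.9 ± 2.51 TPM. Psat1 and Phgdh, enzymes of serine synthesis, fell (log2 fold changes -1.94 and -1.36). Among immediate early genes 10 of 12 measured rose (Fosl1 counting under each of its 2 gene identifiers), Fosb (log2 fold change 2.33) among them, Nr4a2 fell (-1.58) and Egr2 did not pass (0.25). Of 41 genes in the list of autophagy and lysosomes only 9 were in the table, and all 9 rose. They included Gabarapl1 (1.08) and Sqstm1 (0.90), which act in autophagosome formation and cargo capture, and Ulk1 (0.99), the kinase that starts autophagy. In the wider GO term lysosome, tested after the table had been seen, 18 of 32 genes rose and 12 fell (Fisher's exact test, adjusted p = 0.491). The camera adjusted p were 0.0155, 0.0137 and 0.0113 for the stress response, immediate early and autophagy lists. Each of the 3 had an adjusted p = 0.273 with an estimated correlation, and none was called after quantile normalization (adjusted p = 0.0855 for each). Heat shock genes rose in 4 of 5 cases (camera adjusted p = 0.234), among them Dnajb4 (log2 fold change 1.18), Hspb1 (1.06) and Hspb8 (0.63), and the co-chaperone Hspa4l fell.

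Of 11 measured genes of the hypoxia response 8 rose, including Bhlhe40, Slc2a1, the glucose transporter GLUT1 (225 ± 6.37 to 1096 ± 52.1 TPM), and Hilpda, a lipid-droplet protein (25.1 ± 3.05 to 205 ± 11.7 TPM, with SOD1-K123R replicate 4 at 223 and the rest of the group at 198 to 200.2). Bnip3l, Lox and Pdk1 fell. The call was marginal: camera gave an adjusted p of 0.0469, median-of-ratios scaling ended it (0.0790), and the list had an adjusted p = 0.439 with an estimated correlation. Glycolysis genes rose in 5 of 6 cases (camera adjusted p = 0.0602, or 0.0327 with no filter on low values; adjusted p = 0.516 with an estimated correlation). Besides Slc2a1 these included Hk2, a hexokinase (19.1 ± 1.41 to 86.5 ± 6.53 TPM), and Pfkfb3 (log2 fold change 1.65), which makes the activator of phosphofructokinase, while Pdk1 fell. Of 6 genes of lactate transport and use, 3 rose and 3 fell (camera adjusted p = 0.907). The 3 that fell were the lactate transporters Slc16a3 (243 ± 21.7 to 76.9 ± 11.8 TPM) and Slc16a7 (17.9 ± 2.98 to 4.68 ± 0.677 TPM) and the lactate dehydrogenase subunit Ldhb (13.1 ± 1.52 to 3.83 ± 0.856 TPM), and the transporter Slc16a1 rose (log2 fold change 0.90).

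Targets of NRF2, the transcription factor of the oxidative stress response, rose in 7 of 9 cases (camera adjusted p = 0.0602, or 0.0489 among genes with a mean TPM of at least 5 and 0.108 after quantile normalization). The list had an adjusted p = 0.516 with an estimated correlation. Hmox1, which degrades heme, rose from 90.8 ± 7.52 to 603 ± 30.2 TPM, Ftl1, the ferritin light chain, from 4721 ± 572 to 16343 ± 1065 TPM and Tkt, an enzyme of the pentose phosphate pathway, by a log2 fold change of 1.58. Gpx2 fell (-0.71) and Osgin1 did not pass (0.26). Only 2 antioxidant enzymes of the list were tested. Of these Txnrd1, a thioredoxin reductase, rose (log2 fold change 0.62) and Msrb3, a methionine sulfoxide reductase, fell (-0.94). All 4 tested genes of copper and metal handling rose, with log2 fold changes of 1.83 for the metallothionein Mt2A, 1.30 for the copper pump Atp7a and 0.59 for Slc31a2. In the list of ferroptosis and iron genes 3 of 5 rose, Hmox1 and Ftl1 among them, and Dhodh (-2.28) and Slc39a8 fell (camera adjusted p = 0.574).

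**Figure D2:**
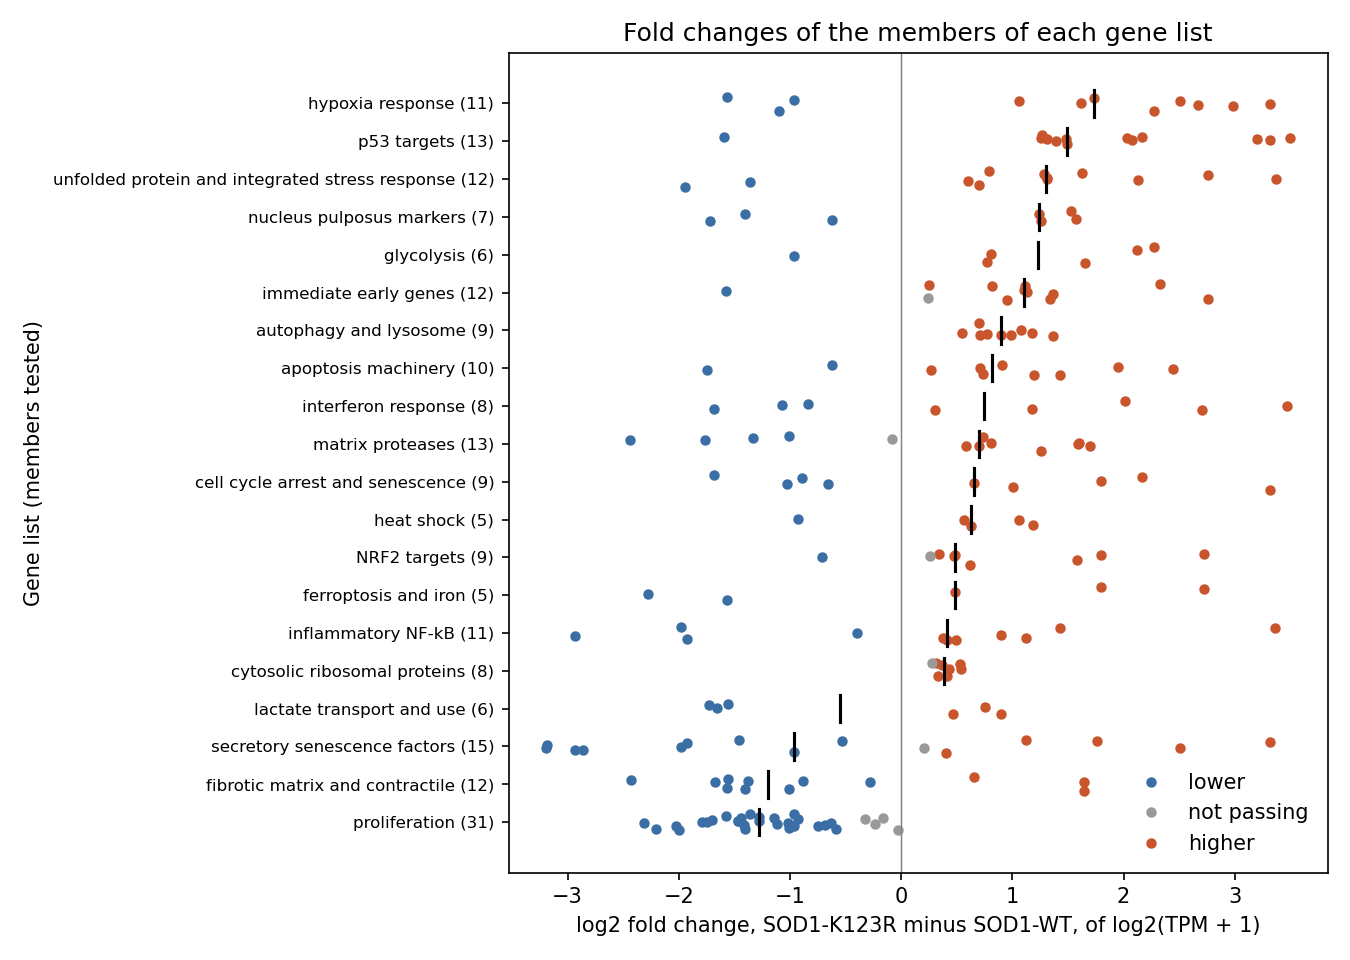
Log2 fold changes (SOD1-K123R minus SOD1-WT) of the tested members of the 20 gene lists with at least 5 of them (points) and their medians (black bars). Orange points passed as higher, blue points as lower and grey points did not pass; proliferation has the lowest median (-1.28) and hypoxia response the highest (1.73).

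Matrix genes were divided. In the fibrotic and contractile list 9 of 12 fell and 3 rose (camera adjusted p = 0.289). Tpm1, a tropomyosin, fell by 2.43 on the log2 scale, whereas Ccn2 and Ccn1, matricellular proteins, rose by 1.64 and 1.65 and Tgfb1 rose by 0.66. Matrix proteases rose in 8 of 13 cases, 4 fell and Adamts2 did not pass (log2 fold change -0.08; camera adjusted p = 0.376). The aggrecanases Adamts4 and Adamts5 moved apart: Adamts4 rose from 16.1 ± 1.03 to 54.6 ± 3.23 TPM and Adamts5 fell from 37.6 ± 5.15 to 6.15 ± 1.16 TPM. Adamts1, a more abundant member of the list, fell from 635 ± 66.7 to 189 ± 36.9 TPM. Adamts7, which cleaves cartilage oligomeric matrix protein, rose (log2 fold change 1.26), with SOD1-WT replicate 4 at 43.5 TPM and the rest of that group at 38.8 to 39.5. Timp3, the 1 protease inhibitor tested, fell by 0.67, a call that ended after median-of-ratios scaling (log2 fold change -0.23, limma adjusted p = 0.0755).

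Of 7 measured markers of nucleus pulposus cells, 4 rose and 3 fell (camera adjusted p = 0.574). Sox9, a transcription factor of chondrogenic cells, rose by a log2 fold change of 1.58 (SE 0.12) from a low level, and Cd24, a surface antigen, rose from 10.1 ± 1.43 to 31.2 ± 6.44 TPM, while Cdh2, which encodes N-cadherin, fell from 9.43 ± 0.432 to 2.96 ± 0.451 TPM. Cartilage matrix genes gave 4 tested members. Dcn, a small proteoglycan, rose (log2 fold change 0.94), Vcan (-1.34) and Acan (-0.62), large proteoglycans, fell, and Prg4 did not pass (0.17). Acan (mean 1.545 TPM in SOD1-WT and 0.645 in SOD1-K123R) and Prg4 (1.195 and 1.475) lay near the filter of 1 TPM.

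Inflammatory genes also moved both ways. Of 11 members of the NF-kB list 7 rose and 4 fell (camera adjusted p = 0.388). Irf1, an interferon-regulated transcription factor, rose from 14.9 ± 1.09 to 163 ± 25.5 TPM and Nfkbia, the inhibitor of NF-kB, from 276 ± 14.5 to 749 ± 87.3 TPM, while the cytokine Il6 fell from 143 ± 29.0 to 17.8 ± 4.12 TPM. The others that fell were Il1b, Ccl2 and Ptges, the last by only 0.40 on the log2 scale. Cd68, the 1 macrophage and leukocyte marker tested, rose from 6.89 ± 1.05 to 26.0 ± 3.56 TPM. Secreted factors of senescent cells fell in 9 of 15 cases, rose in 5 and did not pass in 1, Plaur (log2 fold change 0.20; camera adjusted p = 0.615). In this list Vegfa, the angiogenic factor, and Gdf15 rose (log2 fold changes 2.51 and 3.32) and Cxcl12, a chemokine, fell (-3.18). In the interferon list 5 of 8 rose and 3 fell (camera adjusted p = 0.388). Tap1 (2.71) and Psmb8 (2.02), which serve antigen presentation, and Rsad2 (3.47), an antiviral protein, rose.

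Genes of the apoptosis machinery rose in 8 of 10 cases, with a camera adjusted p of 0.0602 that became 0.0248 when list members were matched by exact symbol alone and 0.0887 with a replicate block (adjusted p = 0.273 with an estimated correlation). Those that rose included Birc2 (log2 fold change 2.44) and Bcl2l1 (1.95), which are inhibitors of cell death, and Apaf1 (1.43), Bcl2l11 (0.91) and Bid (0.27), which promote it. Bcl2l1 read 10.6 TPM in SOD1-WT replicate 3 and 13.3 to 13.9 TPM in the rest of that group. Casp12 and Casp9_v1, the table's name for a caspase 9 gene, fell. Of 4 tested cholesterol genes 2 rose, among them the sterol-dependent brake Insig1 (log2 fold change 3.24), and 2 fell, among them Acat2 (-1.25). Insig1 read 493 TPM in SOD1-K123R replicate 4 and 574 to 587 TPM in the rest of its group.

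The transcripts encoded by mitochondrial DNA that were in the table split by kind. Of 13 mitochondrial mRNAs in the list only 3 were in the table, and the others were not analysed here. These 3 fell, namely Mt-co2 (log2 fold change -1.41), a subunit of cytochrome oxidase, and Mt-nd4 (-1.38) and Mt-nd4l (-1.65), subunits of complex I. Their summed TPM went from 13305 ± 2947 to 4716 ± 608. The 2 mitochondrial rRNAs, singled out after their values were seen, rose from a summed 165 ± 31.6 to 1066 ± 167 TPM. None of the 50 nuclear-encoded respiratory-chain genes of the list was among the genes analysed here. Of 8 cytosolic ribosomal protein genes 7 rose by small amounts (camera adjusted p = 0.0988), such as Rpl12 (log2 fold change 0.53), Rpl30 (0.54) and Rpl28 (0.41), and Rps18 did not pass (0.28), but 1 of 8 rose after quantile normalization (camera adjusted p = 0.984).

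**Figure D3:**
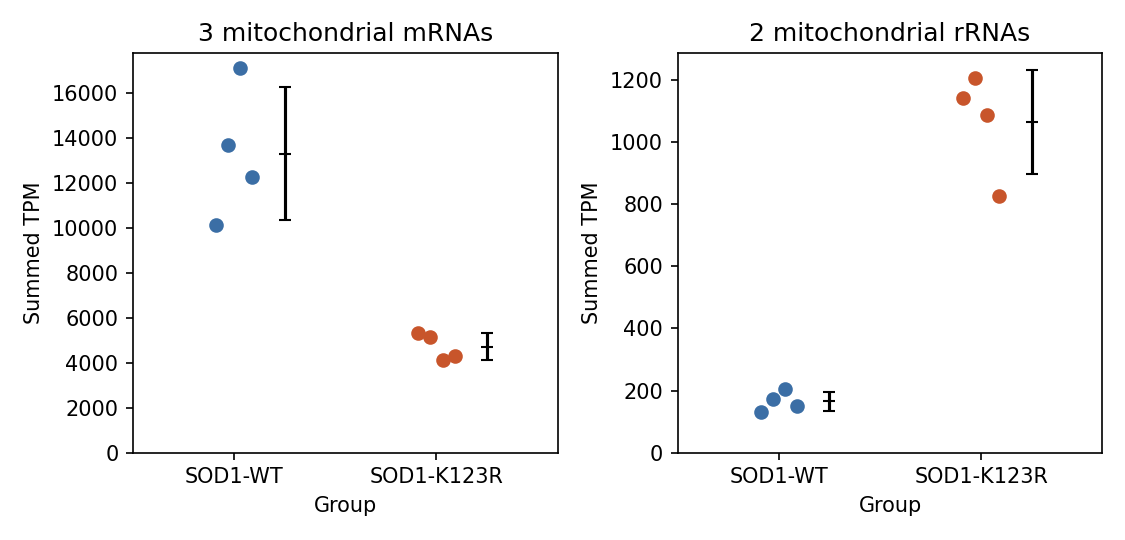
Summed TPM of the 3 mitochondrial mRNAs and of the 2 mitochondrial rRNAs in each library (points), with the mean and SD of each group (bars, n = 4). The mRNA sums of SOD1-K123R lie below every SOD1-WT sum, and the rRNA sums lie above every SOD1-WT sum.

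Markers of other cell types were few in the table. Scx (log2 fold change -1.38) and Thbs4 (-0.63), of tendon and outer disc, fell, although the call for Thbs4 ended after median-of-ratios scaling (log2 fold change -0.21, limma adjusted p = 0.255). Of the bone markers Runx2 rose (1.38) and Ibsp fell (-2.02). Ncam1, of glia and muscle, fell (-0.99), while Mcam, of pericytes, and Fabp4, of adipocytes, rose (1.56 and 0.50). The call for Fabp4 was lost in 4 of the 8 fits that left out 1 library. No endothelial marker passed the expression filter, and no erythroid marker was analysed here.

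The counts of members that rose and fell were the same for every list when adjusted over the list alone. They cover only members in the table, and most lists were incomplete. Tested were 31 of 38 named proliferation genes, 13 of 25 p53 targets and 9 of 28 NRF2 targets. For glycolysis they were 6 of 21, and for cytosolic ribosomal proteins 8 of 47. Camera called 6 of the 20 lists tested, and 0 were called with an estimated correlation (lowest adjusted p = 0.273). By fry, which asks whether the members of a list move on balance one way, 19 of 20 passed. Fry does not compare a list with the other genes, and 95.7% of tested genes passed, so nearly any list could pass. Lactate transport and use, with 3 higher and 3 lower, was among those that did (fry adjusted p = 0.000502). The count is therefore no evidence that members of a list moved together.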

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

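Libraries were compared within each group for the TPM of the genes reported by the naming rule, the TPM sum and the mitochondrial sums by a rule set in advance; the tests of mitochondrial and clock genes discussed under other observations were chosen only after results had been seen. In 6 of 188 groups of 4, a single library stood apart from its group by more than Dixon's limit, where chance alone sets apart about 1 in 20 groups, or 9.4.

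In SOD1-K123R cells, replicate 2 was low for Rem2 (156 TPM, the others 177 to 181). Replicate 4 was low for Gadd45a (425.38 TPM, the others 561 to 586) and Insig1 (493.06 TPM, the others 574 to 587), and high for Hilpda (222.7 TPM, the others 198 to 200.2). In SOD1-WT cells, replicate 4 was high for Adamts7 (43.45 TPM, the others 38.8 to 39.5), and replicate 3 was low for Bcl2l1 (10.56 TPM, the others 13.3 to 13.9). The difference between the groups exceeded each of these gaps, and each of these 6 genes passed without the library named.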

How the results depend on the processing

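Chosen only after results had been seen were exact-symbol matching, the counts of list members, the clock and mitochondrial rRNA measures, the GO and KEGG tests, the count of nuclear respiratory genes and the test of whether the table is complete. Sod1 was not analysed here, so its planned test was not run. At a mean TPM of at least 5, where fewer genes were tested, 948 genes were higher and 897 lower, against 1289 and 1476 (at least 2-fold 576 and 729). The balance of all calls therefore turned. All 1845 genes passing there had passed in the main fit in the same direction, so the turn came from the genes that the filter left out. After median-of-ratios scaling, which shifted the typical log2 fold change by 0.39, 1359 genes were higher and 1363 lower, and 1122 and 555 at least 2-fold, against 751 and 1036. After quantile normalization, which shifted it by 0.20, the 2-fold counts were 851 and 802. Camera called 2 lists after quantile normalization, 0 with an estimated correlation, 7 with exact symbols and 9 with no filter on low values, and fry 19; the cause was not tested. The 3 gained with no filter were NRF2 targets (adjusted p = 0.0327), glycolysis (0.0327) and apoptosis (0.0214). The call for hypoxia genes held in 13 of 18 alternatives (adjusted p 0.0214 to 0.0870). Proliferation and p53 lists were called in 18 of 18, and NRF2 targets, not called otherwise, in 3. After median-of-ratios scaling 23 proliferation genes still fell and 12 p53 targets still rose. That scaling takes most genes as unchanged, and few rows lay near a fold of 1, so it cannot exclude a difference in scaling. Leaving out 1 library left 26 to 28 proliferation genes lower, so no single library was needed for these calls.

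Rpl12 turned to a log2 fold change of -0.00107 under quantile normalization (adjusted p = 0.991), and Rpl28 no longer passed. Among genes named by the rule, Timp3 and Thbs4 no longer passed after median-of-ratios scaling. Members named for going against their list were not followed singly. The falls of Ptges (log2 fold change -0.40) and Areg (-0.53) were close in size to the typical shift of 0.39 under that scaling. Fabp4 no longer passed without SOD1-WT replicate 2 (0.44), SOD1-WT replicate 4 (0.35), SOD1-K123R replicate 1 (0.47) or SOD1-K123R replicate 3 (0.40). Leaving out each library in turn gave 1254 to 1303 genes higher, 1420 to 1497 lower, 708 to 767 and 975 to 1090 at least 2-fold, and 6 to 7 lists. KEGG pathways that leaned one way fell from 9 to 1 after median-of-ratios scaling.

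With the replicate number as a block (paired fit) 2743 genes passed against 2765, and 5 lists were called, hypoxia being lost (adjusted p = 0.0540). Same-numbered libraries did not deviate together (correlations -0.35 to 0.05), and 0 of 4 numbers correlated best with their own.

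Of 35 splits of the libraries into 4 and 4, 1, the real one, gave as many passing genes (2765; highest other 0 by limma, or 214 at an unadjusted p under 0.05 against 2767). As the genes may have been chosen for a difference between these groups, the splits cannot exclude chance. The largest TPM sum, 243393, lies far below the full total of TPM over all genes. The table is therefore partial, and depth is unknown. Whether the choice of rows caused the scarcity of genes near a fold of 1 was not tested.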

Other observations

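All tests in this part, and the genes named with them, were chosen only after results had been seen. Among GO terms of the deposited annotation, 25 of 402 leaned to one direction among passing genes by Fisher's exact test with Benjamini-Hochberg adjustment, 21 to higher and 4 to lower, and 20 of the 25 also passed after median-of-ratios scaling. Genes of DNA replication initiation were lower in 12 of 12 cases (adjusted p = 0.0210), among them Cdc45 (log2 fold change -2.28), a helicase cofactor, Ccne1 (-1.79), the cyclin of S-phase entry, and Orc6 (-1.36), of the origin recognition complex. The broader GO terms DNA replication (6 higher, 16 lower, adjusted p = 0.374), cell division (10 higher, 23 lower, 0.352), cell cycle (7 higher, 4 lower, 0.696) and mitotic cell cycle (9 higher, 12 lower, 0.979) did not pass. The KEGG pathway DNA replication was lower in 11 of 11 cases (adjusted p = 0.0386, but 0.0633 after median-of-ratios scaling). Single-stranded DNA binding genes were lower in 23 of 24 cases, including Prim1 (-2.44), a primase subunit. Genes of smoothened signaling were lower in 11 of 11 cases (adjusted p = 0.0296). These included Smo itself (-1.06), Boc, a co-receptor for Hedgehog ligands (34.4 to 7.82 TPM), and the ciliary transport gene Ift172 (-1.12). Cilium assembly genes fell in 26 cases and rose in 6 (adjusted p = 0.0296, but 0.0571 after median-of-ratios scaling).

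In the other direction, sequence-specific transcription factors were higher in 63 cases and lower in 24 (adjusted p = 0.000107). Genes annotated to the cellular response to lipopolysaccharide rose in 16 of 19 cases and fell in 1, Plscr4 (adjusted p = 0.00388). The separate term response to lipopolysaccharide did not lean either way (9 higher, 8 lower, adjusted p = 0.912). Genes of autophagosome assembly rose in 13 of 15 cases (adjusted p = 0.0467, but 0.0625 after median-of-ratios scaling) and the KEGG autophagy pathway in 16 of 20 (0.0498, but 0.104). The GO terms autophagosome (8 higher, 3 lower, adjusted p = 0.437), lysosome (18 higher, 12 lower, 0.491) and lysosomal membrane (12 higher, 8 lower, 0.601) did not pass. Structural constituents of the ribosome rose in 26 of 46 cases and fell in 7 (adjusted p = 0.0116, and 0.000756 after median-of-ratios scaling), and the cytosolic large ribosomal subunit in 8 of 13 with 0 lower (0.0403, and 0.0146), while the KEGG pathway Ribosome did not pass (6 higher, 5 lower, 0.972). These terms were not tested after quantile normalization, which removed most of the calls of the fixed ribosomal list. In the Hippo signaling pathway of KEGG 16 of 19 rose and 2, Areg and Birc5, fell (adjusted p = 0.0386, and 0.00914 after median-of-ratios scaling). They included Ccn2, Sav1 (log2 fold change 1.15), a scaffold of the Hippo kinases, and Wnt11 (2.80). Long noncoding RNAs passed as higher in 117 cases and lower in 99, against 1166 and 1371 for protein-coding genes (Fisher's exact p = 0.0229).

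Clock genes driven by E-box elements rose together. A list of 12 was written after the values of its tested members had been seen; 9 were tested, all 9 rose, and all 9 also rose in each alternative. Besides Nr1d1, Bhlhe41 and Bhlhe40 they were Dbp (9.26 to 52.9 TPM), Ciart (2.05 to 15.8 TPM), Cry2, Nr1d2, Per1 and Tef. A difference in circadian phase, from the hour of harvest or of a medium change, is a candidate explanation, and would lower the genes driven in the opposite phase, but 0 of these RORE-driven genes were tested. The GO term for circadian regulation of gene expression did not pass (10 higher, 2 lower, adjusted p = 0.139), phase and an effect of the substitution cannot be told apart here, and a biological explanation was not tested.

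The 3 mitochondrial mRNAs in the table, of 13 in the list, fell while the 2 mitochondrial rRNAs rose. The pattern is known for these genes only. Less mitochondrial RNA of every kind, as from fewer mitochondria, would lower both and cannot alone give the whole pattern, since the rRNAs had a median log2 fold change of 2.88. Greater carry-over of RNA without a poly(A) tail in the SOD1-K123R libraries may account for the rRNAs, and would also raise replication-dependent histone mRNAs. Of these a single gene, H1f2, was tested (log2 fold change 1.31, against a median of -1.28 for proliferation genes), which is too few to decide. If the rRNAs rose by carry-over, fewer mitochondria stay open as the source of the lower mRNAs, and of the nuclear respiratory genes that would test this, 0 were tested; a change in mitochondrial RNA processing or stability stays open too, untested.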
